A study of Mus musculus with 17 samples.

How the data were processed

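RNA was sequenced from 17 libraries in 8 groups. The samples came from ID8, a mouse ovarian surface epithelial cancer line, from tumours grown from it, from ascites, and from healthy ovary and intestine. Per the labels' protocols, total RNA was extracted with Trizol and made into directional libraries with a modified NEBNext Ultra II kit. The submitters' processing notes name the aligners HISAT and HISAT2, the counting tool featureCounts and the test package DESeq2. The version of each was not given in the sources used here. Those notes name both hg19 and mm39 as genome builds, so no coordinates were printed. The deposited values were whole-number read counts per Ensembl gene, as the authors' counting produced them, for 43629 genes, of which 39055 had at least 1 count in the libraries used. The 2 deposited files held identical tables. The table held no summary lines such as unassigned reads, and 1 of its columns, headed as a subcutaneous tumour, matched no sample in the labels and was not used here. Gene names were looked up by identifier in the reference name table, where 42462 identifiers matched, and 157 symbols belonged to more than 1 identifier.

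Libraries were grouped by their labels into the cell line (n = 1), orthotopic tumours (n = 3), subcutaneous tumours (n = 2), the first ascites tap (n = 3), the second ascites tap (n = 3), tumours on the intestine (n = 3), healthy ovary (n = 1) and healthy intestine (n = 1). The labels did not say which samples came from the same animal, so the p-values measured only the spread between these samples. Total counts ran from 12031221 to 38902048 per library, with a median of 27342134. A count of 0 in a group was bounded by 3 counts over that group's total, scaled like the reported CPM. Folds against such a group were given as lower bounds. These bounds covered counting error only, since the reads carried no molecular identifiers.

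Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with more than 0.5 CPM (reads of a gene scaled to the library total) in at least 2 libraries were tested, which left 22671 genes. Libraries were scaled by the trimmed mean of M values (TMM), and all 17 libraries were fitted in 1 quasi-likelihood model with robust dispersion and 9 residual degrees of freedom. Genes passed at an adjusted p under 0.05 by Benjamini and Hochberg's method over all genes tested. The model gave 10 comparisons, 5 between replicated groups and 5 against a single library. A comparison with a single library assumes that this lone library varies like the other groups and has no replicate check. CPM and list levels in the results were scaled to the library total over the tested genes times its TMM factor. These factors ran from 0.70 in tumour on the intestine 2 to 1.37 in subcutaneous tumour 3. The filters, the split of genes at 1 CPM in healthy intestine and olfactory receptor CPM used the library total alone. Means in CPM are given with the SD between libraries, and log2 fold changes with their standard error (SE). In every comparison the first group named is the one that a positive log2 fold change favours.

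The tests of the 10 comparisons and of the lists, the gene lists and the rule for named genes were fixed before the data were examined. Tests and alternatives chosen later are named as such where they are given. The rule took up to 8 genes in each direction per comparison between replicated groups, and up to 5 against a single library. These were the largest log2 fold changes among genes that passed, with an absolute log2 fold change of at least 1, a mean of at least 10 CPM in the higher group and no overlap between the groups. Clone names, numbered gene models and antigen receptor segments were left out. Up to 4 members of each list were named beside them, by smallest p, and members whose values per library are described.

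The 33 lists covered tumour cell states and cell types. The lists of cell states were epithelial, mesenchymal, EMT (epithelial to mesenchymal transition) transcription factors, stemness, proliferation, hypoxia and glycolysis, TGF-beta and YAP targets, interferon response, MHC class I presentation, MHC class II presentation, immunosuppression and ovarian carcinoma. The immune and blood lists were T cell, B cell, plasma cell, NK and cytotoxic, macrophage, large peritoneal macrophage, neutrophil, dendritic cell and erythroid. The stromal and tissue lists were endothelial, fibroblast, smooth muscle, skeletal muscle, adipocyte, mesothelial and ovarian surface epithelial, keratinocyte, granulosa and steroidogenic, oocyte, intestinal epithelium, enteric neuron and glia, and pancreatic acinar. Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 33 lists of a comparison, and again with an estimated correlation and with fry. List levels per library were means of log2(CPM + 1). Where members were at 0 in a whole group, the list median was also computed with those members at their bound.

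The alternatives were DESeq2 1.42.0 with its own test, DESeq2's size factors in edgeR, library size alone, no filter, a filter of 1 CPM in 3 libraries, a fold minimum, fits of only the groups compared, the second tap in place of the first, leaving out each replicate, the replicate number as a block, the series of library names in the labels (S, SM and SCT) as a covariate, and a pseudocount of 0.25 for list levels. Alternatives added after the data had been seen left out the 3 libraries with the most detected genes, kept only SM libraries, kept only genes under 1 CPM in healthy intestine, or used the mean of both taps.

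The fit was tested on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold. In the comparison of the first tap with orthotopic tumours it recovered 31 and 79 of them among 21477 genes, and 5.17% of its calls were false. For subcutaneous against orthotopic tumours it recovered 13 and 65 among 21493 genes, and 1.27% of its calls were false. For orthotopic tumours against the single cell line library it recovered 2 and 37 among 21440 genes, with no false call. Camera called none of 19 unchanged lists on simulated data in each of the comparisons it was tested for. The simulated genes varied independently and their lists were drawn at random. This result therefore does not cover lists whose genes vary together, as those of a cell type do.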

Results

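The series measured gene expression by total RNA sequencing in mouse ovarian tumours grown from ID8 cells at different sites. The label of the line describes it as mouse ovarian surface epithelium. Its cells were put under the skin or into the ovary (orthotopic), and the ovarian tumours went on to ascites, tapped in turn, and to solid tumours on the intestine. The data hold 3 orthotopic tumours, 2 subcutaneous tumours, 3 libraries each of the first and second ascites tap, 3 tumours on the intestine, and 1 library each of the cultured line, healthy ovary and healthy intestine. Total counts were lowest in tumour on the intestine 1, at 12031221, and highest in orthotopic tumour 1, at 38902048. Replicates differed most under the skin, where the correlation of log CPM across genes was 0.822, against 0.954 to 0.967 between orthotopic tumours. Subcutaneous tumour 3 had 33393 genes with a count, first tap 3 had 32846 and second tap 1 had 32775, while the other libraries had 21157 to 26838.

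The study asks where ID8 cells stand between epithelial and mesenchymal states at each site. The epithelial list holds junction and keratin genes such as Cdh1, Cldn7 and Epcam, and the mesenchymal list holds matrix and cytoskeleton genes such as Vim, Fn1 and Col1a1. The mean epithelial level was 2.46 in the cell line, between 2.36 and 3.25 in orthotopic tumours, 3.67 and 3.77 in subcutaneous tumours, between 2.15 and 3.33 in both taps, and between 5.49 and 6.96 in tumours on the intestine. Healthy ovary stood at 6.19 and healthy intestine at 6.23. The mesenchymal level was 5.81 in the cell line, between 7.29 and 7.62 in orthotopic tumours, 6.34 and 8.06 in subcutaneous tumours, between 4.99 and 5.97 in the taps, and between 5.54 and 7.42 in tumours on the intestine. Cdh1, the adhesion protein of epithelial junctions, had 94.0 CPM in the cell line, 5.52 to 14.4 CPM in orthotopic tumours and 442 to 1775 CPM in tumours on the intestine. These levels are given without a test. Each is the level of a sample with its host cells, so it does not show the state of ID8 cells alone. The fibroblast level was 1.86 in the cell line, between 4.9 and 5.88 in orthotopic tumours and between 2.60 and 3.26 in the taps.

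**Figure D1:**
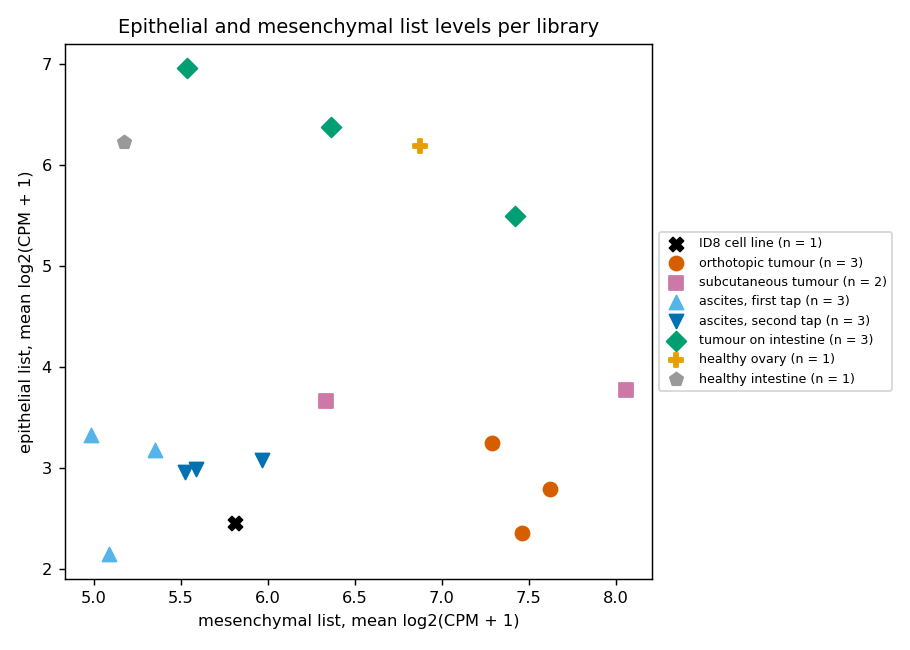
Each point is 1 library, with the mean log2(CPM + 1) of the mesenchymal list on the horizontal axis and of the epithelial list on the vertical axis, coloured by group. Tumours on the intestine sit between 5.49 and 6.96 on the epithelial axis, above every other tumour and ascites library, and the ascites taps sit between 4.99 and 5.97 on the mesenchymal axis.

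**Figure D2:**
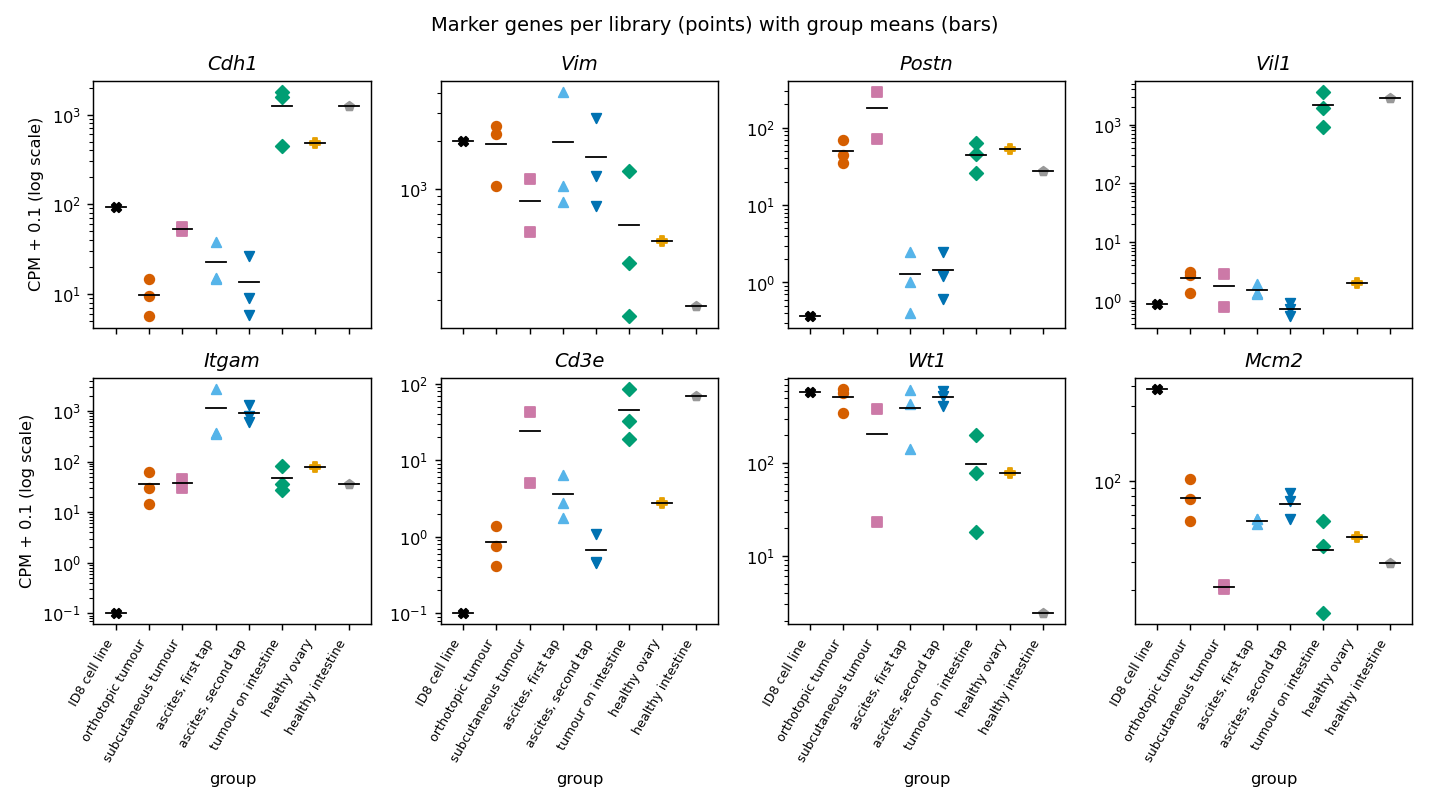
Points are CPM plus 0.1 on a log scale in each library for Cdh1 (epithelial junction), Vim and Postn (mesenchymal), Vil1 (intestinal epithelium), Itgam (myeloid cells), Cd3e (T cells), Wt1 (mesothelium and ovarian surface) and Mcm2 (DNA replication), and bars are group means. Itgam was at 0 in the cell line, and Postn was far lower in the taps than in the solid tumours.

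Vessel, blood and macrophage genes stood above the cultured line in orthotopic tumours, and cell cycle genes stood below it. This comparison asks what changes when ID8 cells grow in the ovary. Kdr, the vascular growth factor receptor of endothelium, had 249 ± 71.8 CPM (SD, n = 3) and was at least 3135-fold higher than in the line, where no count was seen. Igfbp5, a secreted binder of insulin-like growth factors, was at least 45084-fold higher. H2-Aa, an MHC class II chain of antigen-presenting cells, was at least 2995-fold higher, and Tgfbi, a secreted matrix protein, at least 3871-fold. Hbb-bs, a haemoglobin chain with near-identical copies, was at least 3071-fold higher, a value that is uncertain for this gene alone. Among genes that fell, Fgf13 changed by -6.72 ± 1.02 (adjusted p = 0.0117), and Grem1, a BMP antagonist, by -6.22. Bdnf, a neurotrophin, changed by -6.00, Ahrr, the repressor of the aryl hydrocarbon receptor, by -6.03 and Ripply1 by -7.69.

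Of 19 proliferation genes in orthotopic tumours, 4 fell and none rose, and 16 fell when adjusted over the list alone. Plk1, a mitotic kinase, changed by -2.65 (adjusted p = 0.0284) and Mcm3, a replication helicase subunit, by -2.75 (adjusted p = 0.0352). The list median was -2.44 (camera adjusted p = 2.17e-14, and adjusted p = 0.31 with an estimated correlation). A set of 8 genes was chosen for expression in the line and in orthotopic tumours. Each was under 1 CPM in both healthy tissues. In the line these genes stood at a median of 390% of their orthotopic mean. That choice favours high values in the line and low values in the healthy tissues. The share of tumour cells in the samples was not taken out of the proliferation values. Endothelial genes rose in 6 of 9 members, macrophage genes in 7 of 11 and MHC class II genes in 5 of 7, and all members of the 3 lists rose when adjusted over the list alone. With members absent from the line set at their bound, the medians were 7.21 for endothelial, 8.21 for macrophage and 8.43 for MHC class II genes. The camera adjusted p was 1.35e-13, 1.95e-17 and 6.75e-14 in that order, and the adjusted p with an estimated correlation was 0.0821, 0.0935 and 0.0935. Fibroblast genes had a median of 5.75, with 2 of 10 higher and 8 when adjusted over the list alone (camera adjusted p = 4.66e-07, and adjusted p = 0.0821 with an estimated correlation). The erythroid list had 3 of 7 members higher, all 7 when adjusted over the list alone, and a bound median of 8.78 (camera adjusted p = 2.14e-07, and adjusted p = 0.276 with an estimated correlation). In the mesenchymal list 3 of 20 genes rose, among them Postn by 7.52 ± 1.63 (adjusted p = 0.0321), and Tnc, both matrix proteins. Adjusted over the list alone, 7 were higher and 2 lower, and the list median was 0.54 (camera adjusted p = 0.0385, and adjusted p = 0.589 with an estimated correlation). Without orthotopic tumour 1 this list call was lost, at a median of 0.39 (adjusted p = 0.0573). The epithelial list did not pass (median 1.52 with absent members at their bound, camera adjusted p = 0.259), with 1 of 24 genes higher over all genes, and 2 higher and 1 lower when adjusted over the list alone. Cdh1 stood at 9.74 ± 4.47 CPM (SD, n = 3) against 94.0 CPM in the line, and its log2 fold change of -3.27 ± 0.83 missed the threshold (adjusted p = 0.0538). In all, edgeR called 537 genes higher and 189 lower, against the lone cell line library. The total was 325 without orthotopic tumour 1, 309 without orthotopic tumour 2 and 391 without orthotopic tumour 3, and 460 when scaled by library size alone.

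Immune and vessel genes also stood above the cultured line in subcutaneous tumours, and cell cycle genes below it. Macrophage genes rose in 9 of 11 members, T cell genes in 11 of 16 and endothelial genes in 7 of 9, and in 11, 14 and 9 when adjusted over the list alone. The camera adjusted p was 6.91e-13, 2.11e-07 and 5.39e-11 in that order, and the adjusted p with an estimated correlation was 0.189, 0.327 and 0.17. In these tumours the 8 genes of the line, under 1 CPM in both healthy tissues, stood at a median of 8.26% of their orthotopic mean in tumour 2. In tumour 3 they stood at 183%. The data hold no healthy skin or fat to choose these genes against, so these values do not measure tumour cells alone. Ptprc, the pan-leukocyte phosphatase CD45, had 772 ± 979 CPM (SD, n = 2) and was at least 9717-fold higher than in the line. Igfbp5 was at least 23561-fold higher, and the MHC class II chains H2-Aa and H2-Ab1 at least 10578-fold and 6336-fold. Cd36, a fatty acid transporter of fat and endothelium, had 667 ± 922 CPM (SD, n = 2), a mean at least 8390-fold higher. These bounds are for the mean of 2 unlike tumours and do not hold for each tumour. Flnc, an actin cross-linker, changed by -5.14 ± 1.14 (adjusted p = 0.0209), Rab3b by -6.77 and Ripply1 by -7.24. The replication-dependent histones Hist1h2bl and Hist1h3g changed by -6.01 and -5.53, values that are uncertain because histone genes have near-identical copies.

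Proliferation genes under the skin fell in 15 of 19 members, and in all 19 when adjusted over the list alone. Mcm2, a replication helicase subunit, changed by -4.21 ± 0.60 and Plk1 by -4.61 ± 0.66 (adjusted p = 0.00687 for each), and the list median was -3.63 (camera adjusted p = 7.77e-20, and adjusted p = 0.19 with an estimated correlation). In the epithelial list 4 of 24 genes rose, and when adjusted over the list alone 12 were higher and 3 lower. Pkp3, a desmosome plaque protein, rose by 6.44 ± 1.53 (adjusted p = 0.0262), Marveld2, a tight junction protein, by 5.51 (adjusted p = 0.0237) and St14, an epithelial protease, by 5.30 (adjusted p = 0.0324). Ocln, a further tight junction protein, had 4.53 ± 0.393 CPM (SD, n = 2) and no count in the line. The epithelial median was 3.27 (camera adjusted p = 0.0263, and adjusted p = 0.481 with an estimated correlation). The keratinocyte level was 2.34 and 5.02 in subcutaneous tumours 2 and 3 against 0.869 in the line, and a share of skin was not tested. The mesenchymal list did not pass (median 0.40, camera adjusted p = 0.328), and its median was -1.12 without subcutaneous tumour 3. In all, 1418 genes were higher and 733 lower than in the lone cell line library, 1026 in total without subcutaneous tumour 2, and 1418 in total with no filter on low counts.

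Ascites cells of the first tap differed from the cultured line by macrophage genes above all. Itgam, an integrin of myeloid cells, had 1147 ± 1360 CPM (SD, n = 3) and was at least 14430-fold higher than in the line. Mrc1, the mannose receptor, was at least 7387-fold higher, C1qb, a complement chain made by macrophages, at least 6892-fold, and Igfbp5 at least 11297-fold. Lyz2, a macrophage lysozyme, was at least 40505-fold higher, uncertain because Lyz1 is a near-identical copy. Pdzrn3 changed by -6.76 ± 0.69 (adjusted p = 0.0049). Cyp1a1, a target of the aryl hydrocarbon receptor, changed by -7.26, Ripply1 by -7.00, Ptx3, a secreted pattern recognition protein, by -6.43 and Mmp16, a membrane metalloproteinase, by -6.03.

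Macrophage genes rose in all 11 members over the line, also when adjusted over the list alone, with a median of 11.55 at the bounds (camera adjusted p = 1.38e-23, and adjusted p = 0.163 with an estimated correlation). Proliferation genes fell in 6 of 19 members, 16 when adjusted over the list alone (median -2.61, camera adjusted p = 1.72e-19, and adjusted p = 0.258 with an estimated correlation). The 8 genes of the line stood at a median of 140%, 50.9% and 109% of their orthotopic mean in first taps 1, 2 and 3, against 390% in the line. The share of tumour cells was not taken out of the values in this paragraph. Among 9 EMT transcription factors 2 fell, and 3 when adjusted over the list alone: Snai1 changed by -3.86 ± 0.60 (adjusted p = 0.0112) and Snai2 by -3.49 ± 0.65 (adjusted p = 0.017), both repressors of Cdh1. The list median was -0.45 (camera adjusted p = 0.013, and adjusted p = 0.341 with an estimated correlation). The mesenchymal list did not pass, with a median of -0.28 and a mean of 0.22 (camera adjusted p = 0.0608), and 1 gene rose and 1 fell. The epithelial list did not pass either (median 1.56 at the bounds, camera adjusted p = 0.296), and Cdh1 had 22.4 ± 13.3 CPM (SD, n = 3) against 94.0 CPM. In all, 706 genes were higher and 251 lower than in the lone cell line library.

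Epithelial, follicle and oocyte genes stood lower in orthotopic tumours than in the lone library of healthy ovary. That library had a smooth muscle level of 6.41, against 3.29 to 4.35 in orthotopic tumours. Its adipocyte level was 7.31 against 2.64 to 5.89, and its ovarian carcinoma level of 4.84 was the highest of all 17 libraries. Whether this sample held tissue other than ovary was not tested. Muc4, a membrane mucin, changed by -11.94 ± 1.93 (adjusted p = 0.0241), with 1964 CPM in ovary and 0.49 ± 0.453 CPM (SD, n = 3) in tumours. Padi1, a protein deiminase, changed by -11.18, Unc5cl by -9.58, Serpina1e by -8.96 and Lrat, the retinol acyltransferase, by -8.84. Haao, an enzyme of tryptophan breakdown, rose by 6.50 ± 0.78 (adjusted p = 0.00794) and Cerk, ceramide kinase, by 3.36 ± 0.57 (adjusted p = 0.0291).

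Epithelial genes fell in 7 of 24 members against healthy ovary, and in 17 when adjusted over the list alone. Cldn7, a tight junction claudin, changed by -6.55 ± 0.66 (adjusted p = 0.0038), Rab25 by -6.47, St14 by -6.31 and Cdh1 by -5.63 ± 0.86 (adjusted p = 0.0178), from 485 CPM in ovary. The list median was -4.19 (camera adjusted p = 1.18e-21, and adjusted p = 0.0484 with an estimated correlation). Among granulosa and steroidogenic genes 2 of 11 fell, and 7 when adjusted over the list alone: Cyp11a1, which makes pregnenolone, by -7.76, and Inhba, an activin subunit, by -6.01 (camera adjusted p = 0.000117, and adjusted p = 0.546 with an estimated correlation). Among 8 oocyte genes 1 fell, and 7 when adjusted over the list alone: Gdf9, an oocyte growth factor, by -5.30 (list median -6.17, camera adjusted p = 9.13e-08, and adjusted p = 0.253 with an estimated correlation). The ovarian carcinoma list, which holds Pax8, Wfdc2 and other Müllerian markers, had a median of -3.89, with 4 of 10 genes lower when adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.422 with an estimated correlation). That call was lost without orthotopic tumour 2 (median -3.58, adjusted p = 0.0547). DESeq2 called 259 genes higher and 521 lower than in the lone ovary library. With edgeR, 2 genes were higher and 134 lower in all. The total was 5 without orthotopic tumour 1, 3 without orthotopic tumour 2 and 17 without orthotopic tumour 3, and 2 of the 14 named genes, Haao and Cldn7, stayed past the threshold in each of these fits.

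Subcutaneous and orthotopic tumours were compared to see how the site of a primary tumour changes it. Genes of squamous epithelium and of lymphocytes stood higher under the skin in the mean of 2 unlike tumours, and 3 genes passed the test. In subcutaneous tumours 2 and 3 the list level was 8.45 and 1.75 for B cell, 4.33 and 2.00 for T cell, 2.34 and 5.02 for keratinocyte and 9.66 and 1.91 for adipocyte genes, and the 8 genes of the line stood at 8.26% and 183% of their orthotopic mean. Mitochondrial genes took 10.7% of counts in subcutaneous tumour 3 and more in tumour 2, against 6.37% to 6.99% in orthotopic tumours and at most 8.30% in any other library, a difference in RNA that goes with the site. Ly6d (ENSMUSG00000034634), a surface protein of squamous epithelium and early B cells, rose by 7.51 ± 0.98, with 117 ± 124 CPM (SD, n = 2) against 0.637 ± 0.329 CPM (SD, n = 3). Lad1 (ENSMUSG00000041782), an anchoring protein of the epidermal basement membrane, rose by 4.59 ± 0.60, and Fabp5 (ENSMUSG00000027533), the epidermal fatty acid binding protein, by 3.90 ± 0.51. The edgeR adjusted p was 0.0401 for each of the 3.

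T cell genes had a median of 4.71 under the skin (camera adjusted p = 4.89e-13), and 15 of 16 were higher when adjusted over the list alone. Icos, a costimulator of T cells, was 5.72 higher and Foxp3, the regulator of regulatory T cells, 3.88 higher (adjusted p = 0.0532 for each). B cell genes had a median of 7.77 (camera adjusted p = 3.85e-07), with all 11 higher when adjusted over the list alone. Without subcutaneous tumour 2 the B cell call was lost (median 0.95, adjusted p = 0.21). Keratinocyte genes had a median of 5.76, with 9 of 10 higher when adjusted over the list alone (camera adjusted p = 1.32e-05), and Krt5, a basal keratin, had 315 CPM in tumour 3. NK and cytotoxic genes had a median of 3.00 (camera adjusted p = 1.2e-05), with 6 of 10 higher when adjusted over the list alone. Epithelial genes had a median of 1.55, with 10 of 24 higher when adjusted over the list alone (camera adjusted p = 0.00476), among them Pkp3 at 4.81 (adjusted p = 0.0532) and St14 at 3.12 (adjusted p = 0.0759). The keratinocyte level was 2.34 and 5.02 in subcutaneous tumours 2 and 3 and 0.79 to 1.02 in orthotopic tumours. The data hold no library of healthy skin, so a share of skin in the epithelial values was not tested. Proliferation genes had a median of -1.21, with 2 of 19 lower when adjusted over the list alone (camera adjusted p = 1.89e-07), as Mcm2 at -1.90 ± 0.48 (adjusted p = 0.0822). Hypoxia and glycolysis genes had a median of -0.88 (camera adjusted p = 0.00304), lost without tumour 3 (median -0.52, adjusted p = 0.213). None of these list calls held with an estimated correlation, where the adjusted p was 0.546 for each. The mesenchymal list did not pass, with a median of 0.16 and a mean of -0.04 (camera adjusted p = 0.356). Its median was -1.48 without tumour 3 (adjusted p = 0.0182) and -0.05 without orthotopic tumour 3.

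At an unadjusted p under 0.05, edgeR had 4690 genes for this comparison, and DESeq2 called 2300 after adjustment. Without subcutaneous tumour 3, which leaves tumour 2 assumed to vary like the other groups, 987 genes were called, without tumour 2 there was 1, and without orthotopic tumour 1, 2 or 3 there was none, with 3178, 3332 and 3897 at an unadjusted p under 0.05. Both subcutaneous libraries carry SCT library names and no other library does, so the series of library names and the site cannot be told apart.

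The first ascites tap was compared with orthotopic tumours to set tumour cells in fluid against the primary tumour. Macrophage and neutrophil genes were higher in ascites, and genes of vessels, fibroblasts and matrix were lower. Timd4 and Cd5l, markers of resident macrophages, rose by 7.64 ± 1.45 (adjusted p = 0.0328) and 7.55 ± 1.61 (adjusted p = 0.0421), and Fcna, a ficolin made by macrophages, by 6.26. Saa3, an acute-phase protein, rose by 6.49 ± 1.33, with 151 ± 46.1 CPM against 1.67 ± 1.67 CPM (SD, n = 3 each). Padi4 and Cxcr2, genes of neutrophils, rose by 6.57 and 6.27, and Hal, histidine ammonia lyase, by 6.89. Sparcl1, a matrix protein of vessels and stroma, changed by -7.22 ± 0.81 (adjusted p = 0.009), and Rgs5, a pericyte marker, by -7.36. Eltd1, an adhesion receptor of endothelium, had 2 counts in all 3 ascites libraries and a ratio of orthotopic to ascites CPM of 792 (95% counting interval 219 to 6539).

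Car3, the carbonic anhydrase of fat and muscle, changed by -11.76, Fndc5, the precursor of irisin, by -7.30, Mfap4, a microfibril protein, by -7.25 and Col8a1, a short-chain collagen, by -7.17. Lyz1 rose by 6.49 and the mast cell protease Mcpt1 changed by -8.20, both uncertain because of near-identical copies. Macrophage genes rose in 6 of 11 members in ascites, and in all 11 when adjusted over the list alone, among them Itgam by 5.00, Cd68 by 3.36 and Csf1r by 3.26 (list median 2.90, camera adjusted p = 8.65e-11, and adjusted p = 0.198 with an estimated correlation). Large peritoneal macrophage genes rose in 5 of 10, and in 9 when adjusted over the list alone, such as F5 by 5.47 and Selp by 4.75 (median 5.11, camera adjusted p = 6.58e-09, and adjusted p = 0.056 with an estimated correlation). Neutrophil genes rose in 2 of 10, and in 8 when adjusted over the list alone, such as Csf3r, the receptor for granulocyte colony-stimulating factor, by 5.06 (median 4.99 at the bounds, camera adjusted p = 2.56e-05, and adjusted p = 0.353 with an estimated correlation). Endothelial genes fell in 5 of 9, and in all 9 when adjusted over the list alone, such as Cdh5 by 5.28 on the log2 scale and Pecam1, for which the value was -2.62 (median -3.95, camera adjusted p = 5.46e-18, and adjusted p = 0.0253 with an estimated correlation). Fibroblast genes fell in 4 of 10, and in 7 when adjusted over the list alone, such as Pdgfrb, which changed by -4.99 ± 0.56 (adjusted p = 0.009), and Lum, by -6.53 (median -3.32, camera adjusted p = 6.07e-12, and adjusted p = 0.0253 with an estimated correlation).

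Mesenchymal genes fell in 7 of 20 members in ascites, and in 10 when adjusted over the list alone (median -2.01, camera adjusted p = 8.61e-12, and adjusted p = 0.127 with an estimated correlation). Those that fell were matrix genes such as Postn (-5.34 ± 0.87, adjusted p = 0.0242), Mmp2 (-6.57), Fbn1 (-4.68) and Col1a2 (-4.35). Among EMT transcription factors 1 of 9 fell, and 5 when adjusted over the list alone: Snai1 changed by -3.35 ± 0.51 (adjusted p = 0.0195), while Zeb1 at -1.38 (adjusted p = 0.0649) and Snai2 at -2.13 (adjusted p = 0.0661) did not pass (list median -1.38, camera adjusted p = 8.79e-05, and adjusted p = 0.14 with an estimated correlation). In the epithelial list 1 gene of 24 fell, Ocln by 3.92 on the log2 scale (adjusted p = 0.0339), also when adjusted over the list alone. The list did not pass (median 0.14, camera adjusted p = 0.867), and its median was -0.24 without orthotopic tumour 2 and -0.02 without first tap 3. Cdh1 had 22.4 ± 13.3 CPM in ascites (SD, n = 3).

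Among lymphocyte genes in ascites, Cd5 was the 1 T cell gene of 16 that rose, by 3.40 (adjusted p = 0.0446), also when adjusted over the list alone, and the list median was 2.09 (camera adjusted p = 1.11e-05, and adjusted p = 0.353 with an estimated correlation). The immunosuppression list had a median of 1.31 (camera adjusted p = 0.0454, and adjusted p = 0.439 with an estimated correlation). Without first tap 2 its median was -0.03 (adjusted p = 0.224), and that call was also lost without orthotopic tumour 2 (median 0.81, adjusted p = 0.0964) or first tap 1 (median 1.45, adjusted p = 0.0877). Its member Arg1, the arginase of alternatively activated macrophages, had 581 ± 325 CPM against 33.7 ± 47.6 CPM (SD, n = 3 each; adjusted p = 0.102). Adipocyte genes had a median of -7.72, with 1 of 8 lower and 6 when adjusted over the list alone (camera adjusted p = 3.83e-07, and adjusted p = 0.229 with an estimated correlation). Skeletal muscle genes had a median of -4.79, with 6 of 10 lower when adjusted over the list alone (camera adjusted p = 0.0215, and adjusted p = 0.546 with an estimated correlation). Ttn, the muscle titin, had 1560 CPM in orthotopic tumour 2, and without that tumour the list median was 1.41 (adjusted p = 0.477), while without first tap 1 the call was lost at -4.37 (adjusted p = 0.117). Dendritic cell genes had a median of 2.37 (camera adjusted p = 0.0359, and adjusted p = 0.455 with an estimated correlation), which was 0.68 without first tap 2 (adjusted p = 0.224).

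In all, 156 genes were higher and 202 lower in ascites, and 4 of the 38 named genes, Eltd1, Rgs5, Sparcl1 and Pdgfrb, stayed past the threshold in every fit without 1 library. The total was 18, 23 and 130 without orthotopic tumours 1, 2 and 3, and 233, 25 and 793 without first taps 1, 2 and 3. It was 668 with the series of library names as a covariate and 0 by edgeR among SM libraries alone (3398 at an unadjusted p under 0.05), which leave 2 per group, while each of these groups holds 1 S library. With library size alone 19 were higher and 64 lower, and in a fit of only these 2 groups 3 were higher and 76 lower.

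The second tap was compared with the first to follow ascites over time. No gene passed in edgeR, with 145 at an unadjusted p under 0.05 and 1 called by DESeq2. On simulated counts the fit for this comparison recovered 23 of 100 4-fold and 74 of 100 16-fold changes. T cell genes had a median of -1.69 (camera adjusted p = 1.54e-18, and adjusted p = 0.136 with an estimated correlation), and no member passed, also when adjusted over the list alone. Cd3e, a chain of the T cell receptor complex, had 0.575 ± 0.369 CPM in the second tap and 3.54 ± 2.46 CPM in the first (SD, n = 3 each). NK and cytotoxic genes had a median of -1.11 (camera adjusted p = 3.1e-09, and adjusted p = 0.136 with an estimated correlation), with Nkg7 at 0.381 ± 0.254 against 1.76 ± 0.854 CPM and Gzmb at 0.0677 ± 0.06 against 0.939 ± 0.953 CPM. Proliferation genes had a median of 0.49 (camera adjusted p = 6.04e-07, and adjusted p = 0.975 with an estimated correlation), which was 0.15 and did not pass without first tap 1 (adjusted p = 0.232). Mesenchymal genes had a median of 0.42 (camera adjusted p = 0.00356, and adjusted p = 0.975 with an estimated correlation). That call was lost without first tap 2 (median 0.18, adjusted p = 0.0867), first tap 3 (median 0.28, adjusted p = 0.166) or second tap 2 (median 0.17, adjusted p = 0.53). The epithelial list did not pass (median -0.06, camera adjusted p = 0.99).

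Tumours on the intestine were compared with orthotopic tumours to set a solid metastasis against its primary tumour. Genes of gut epithelium dominated the difference. Sis, the sucrase-isomaltase of the brush border, had 7273 ± 3890 CPM (SD, n = 3) against 0.0346 ± 0.0599 CPM (SD, n = 3), a log2 fold change of 17.43 ± 2.64 (adjusted p = 0.0017). Reg3b, an antimicrobial lectin of the gut, was at least 57006-fold higher, Apoa4, an apolipoprotein of enterocytes, at least 36257-fold and Clec2h at least 31198-fold. Cyp2c55 was at least 28091-fold higher and Enpp7, the alkaline sphingomyelinase of the gut, at least 14004-fold. Cdhr2, a brush border cadherin with 2 counts over the 3 orthotopic libraries, had a ratio of 105293 (95% counting interval 29148 to 869438). Ugt2b34 was at least 16883-fold higher, uncertain because of near-identical copies.

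Fkbp6, a meiotic protein, was at least 316-fold lower in tumours on the intestine. Emx2, a homeobox gene of the urogenital tract, changed by -7.21 ± 1.19 (adjusted p = 0.00281) and Fndc5 by -6.70 ± 1.08 (adjusted p = 0.0025). Ano4 changed by -6.84, Sema5b by -6.32 and Cela3b, a pancreatic elastase, by -6.39. Slc1a6, a glutamate transporter with 2 counts in tumours on the intestine, had a ratio of orthotopic to intestinal CPM of 326 (95% counting interval 90.1 to 2689), and the mast cell protease Mcpt2 changed by -6.99, uncertain because of near-identical copies. Among epithelial genes 17 of 24 rose, and 18 when adjusted over the list alone. Cldn7 rose by 9.01 ± 0.67 (adjusted p = 0.000167), Cdh1 by 7.01 ± 0.84 (adjusted p = 0.000627), Pkp3 by 7.52 and St14 by 7.40. The list median was 4.37 (camera adjusted p = 1.28e-12, and adjusted p = 0.129 with an estimated correlation). Intestinal epithelium genes moved with them: 17 of 18 rose, and 17 were higher and 1 lower when adjusted over the list alone, such as Vil1, the brush border villin, by 9.86 ± 0.80 (adjusted p = 0.000167), Cdh17 by 11.88 and Fabp2 by 13.91 (median 11.89 at the bounds, camera adjusted p = 2.02e-22, and adjusted p = 0.0715 with an estimated correlation). The median gut marker stood at 71.1%, 98.2% and 33.0% of its CPM in healthy intestine in tumours 1, 2 and 3. Of the 2354 genes that rose, 95.1% had at least 1 CPM in healthy intestine, against 82.9% of the 1163 that fell and 66.9% of all genes tested.

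Smooth muscle genes rose in 7 of 9 members in tumours on the intestine, and in 7 when adjusted over the list alone, such as Myh11 by 5.04 and Acta2 by 3.02 (median 3.04, camera adjusted p = 3.88e-06, and adjusted p = 0.129 with an estimated correlation). T cell genes rose in 13 of 16 and 1 fell, and 15 rose and 1 fell when adjusted over the list alone. Cd3e rose by 5.92 (adjusted p = 0.00363) and Cd8a by 6.37 (adjusted p = 0.00496), while Pdcd1, the inhibitory receptor PD-1, changed by -4.21 (adjusted p = 0.0218; list median 4.08, camera adjusted p = 3.35e-08, and adjusted p = 0.334 with an estimated correlation). Cytotoxic genes rose in 7 of 10, and in 8 when adjusted over the list alone, such as the granzymes Gzma by 10.31 and Gzmb by 6.43 (median 2.95, camera adjusted p = 5.1e-06, and adjusted p = 0.241 with an estimated correlation). MHC class I genes rose in 8 of 9, and in all 9 when adjusted over the list alone, such as H2-K1 by 3.05, uncertain because of its near-identical relatives (median 3.05, camera adjusted p = 3.88e-06, and adjusted p = 0.349 with an estimated correlation). Plasma cell genes rose in 4 of 8, and in all 8 when adjusted over the list alone, such as Igha, the heavy chain of IgA, by 5.74 (median 3.68, camera adjusted p = 0.000143, and adjusted p = 0.241 with an estimated correlation). The interferon response list had 3 of 15 genes higher, and 6 when adjusted over the list alone, such as Irf7 by 3.40 (median 2.06, camera adjusted p = 0.0153, and adjusted p = 0.748 with an estimated correlation), lost without tumour on the intestine 2 (median 0.59, adjusted p = 0.187). Healthy intestine expressed these lists too, at a level of 4.33 for T cell genes against 2.45 to 3.70 in the tumours on it, 7.30 against 5.86 to 6.55 for plasma cell, 8.42 against 7.45 to 8.79 for MHC class I and 6.18 against 6.55 to 7.03 for smooth muscle genes.

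The mesenchymal list of these tumours had a median of -0.92 with no member past the threshold, also when adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.669 with an estimated correlation). Vim had 597 ± 608 CPM against 1902 ± 753 CPM in orthotopic tumours (SD, n = 3 each; adjusted p = 0.191) and Cdh2, the neural cadherin, a log2 fold change of -2.43 (adjusted p = 0.0742). Among EMT transcription factors 2 of 9 fell, also when adjusted over the list alone: Zeb1 changed by -1.46 ± 0.34 (adjusted p = 0.016) and Snai2 by -1.89 ± 0.53 (adjusted p = 0.0318). The median of that list was -1.05 (camera adjusted p = 0.0211, and adjusted p = 0.44 with an estimated correlation). Both list calls were lost without tumour on the intestine 1, at -0.60 and -0.80 (adjusted p = 0.0975 for each). In tumour 1 the mesenchymal level was 5.54 and that of EMT transcription factors 2.87, against 5.18 and 3.29 in healthy intestine. The 8 genes of the line stood at a median of 2.56%, 30.8% and 72.9% of their orthotopic mean in tumours 1, 2 and 3. In healthy intestine, where they were chosen to be low, they stood at 1.85%. Of TGF-beta and YAP targets 1 of 12 fell, also when adjusted over the list alone: Axl, a receptor kinase, changed by -2.43 ± 0.53 (adjusted p = 0.0118; list median -1.42, camera adjusted p = 0.0256, and adjusted p = 0.481 with an estimated correlation). Granulosa and steroidogenic genes fell in 5 of 11, and in 6 when adjusted over the list alone, such as Inha, the inhibin alpha chain, by 6.26 on the log2 scale (median -4.78, camera adjusted p = 0.000143, and adjusted p = 0.44 with an estimated correlation). The stemness list did not pass (median 1.05, camera adjusted p = 0.983), with 2 of 13 genes higher and 1 lower, also when adjusted over the list alone: Prom1 rose by 7.32 (adjusted p = 0.0128), Klf4 by 2.82 (adjusted p = 0.0318) and Bmi1 changed by -1.37 (adjusted p = 0.0316).

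In all, 2354 genes were higher and 1163 lower in tumours on the intestine, and 30 of the 45 named genes stayed past the threshold in every fit without 1 library. The total was 1435, 1211 and 2060 without orthotopic tumours 1, 2 and 3, 1649 and 1371 without tumours on the intestine 1 and 2, and 654 among SM libraries alone. Among the 7508 genes under 1 CPM in healthy intestine, 116 were higher and 199 lower, and 1 and 4 when adjusted over these genes alone.

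**Figure D3:**
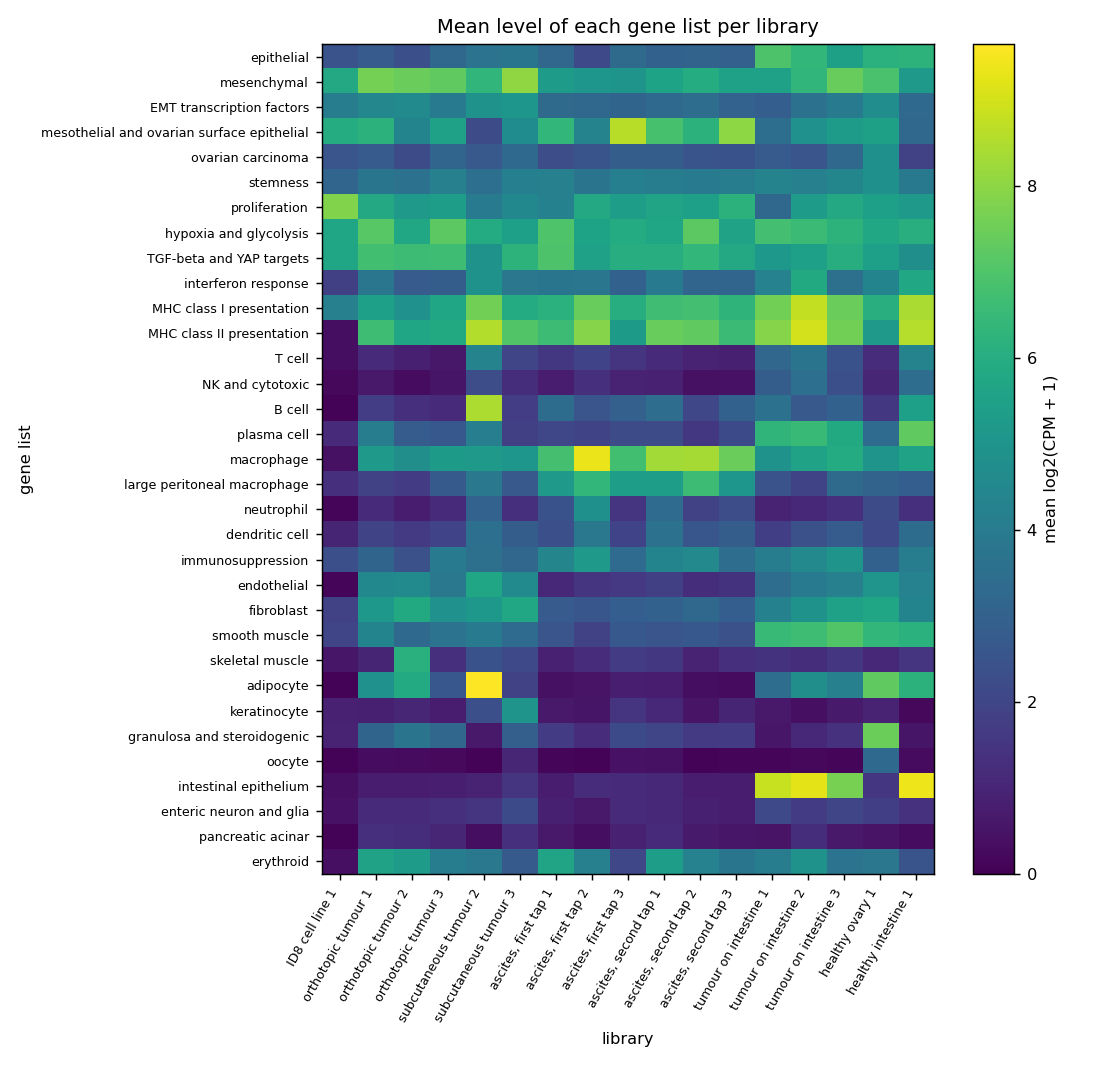
Rows are the 33 gene lists, columns are the 17 libraries, and colour is the mean log2(CPM + 1) of the list. Intestinal epithelium genes are bright in tumours on the intestine and healthy intestine, macrophage genes in ascites, and B cell and adipocyte genes in subcutaneous tumour 2.

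Solid and fluid metastases were compared through tumours on the intestine and the first tap. Gut, epithelial and smooth muscle genes were higher in the solid tumours, and macrophage genes were lower. Cdx2, the intestinal homeobox factor, rose by 13.10 ± 1.97 (adjusted p = 0.00184), with 239 ± 188 CPM (SD, n = 3) and 2 counts over the 3 ascites libraries, a ratio of 10646 (95% counting interval 2947 to 87911). Reg3b rose by 14.39 ± 2.24 (adjusted p = 0.00633), Fcgbp, a mucus protein, by 13.13, and Muc3, a gut mucin, by 13.12. Oit1 was at least 5832-fold higher. Sprr2a1 rose by 14.67 and Sprr2a2 was at least 1374-fold higher, both uncertain because of near-identical copies.

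Most named genes that fell were myeloid: Cd5l changed by -7.67 ± 1.65 (adjusted p = 0.0126), Padi4 by -7.39, Cxcl2, a chemokine for neutrophils, by -7.13 and its receptor Cxcr2 by -6.53. Marco, a scavenger receptor, changed by -5.96, Fcna by -5.64, Clec4d, a myeloid lectin, by -5.32 and Mybpc3, a myosin binding protein, by -5.11. Epithelial genes rose in 15 of 24 members over ascites, and 16 were higher and 1 lower when adjusted over the list alone (median 5.10, camera adjusted p = 2.07e-14, and adjusted p = 0.0982 with an estimated correlation), with Cdh1 5.81 ± 0.79 higher (adjusted p = 0.00114). Intestinal epithelium genes rose in 16 of 18, and in 17 when adjusted over the list alone (median 10.75, camera adjusted p = 6.78e-25, and adjusted p = 0.0124 with an estimated correlation). Smooth muscle genes rose in 8 of 9, also when adjusted over the list alone (median 5.12, camera adjusted p = 2.18e-13, and adjusted p = 0.0124 with an estimated correlation). Mesenchymal genes rose in 9 of 20 and 1 fell, and 9 rose and 2 fell when adjusted over the list alone: Postn by 5.20, Fbn1 by 4.08 and Col1a2 by 3.71 were higher (median 1.24, camera adjusted p = 0.00523, and adjusted p = 0.548 with an estimated correlation). The mesenchymal call was lost without tumour on the intestine 3 (median 0.70, adjusted p = 0.179). Macrophage genes fell in 8 of 11, and in 9 when adjusted over the list alone, such as Cd68, which changed by -3.67, and Itgam, by -4.58 (median -2.95, camera adjusted p = 9.01e-06, and adjusted p = 0.466 with an estimated correlation). Enteric neuron and glia genes had a median of 1.67, with 1 of 8 higher, also when adjusted over the list alone (camera adjusted p = 0.0446, and adjusted p = 0.517 with an estimated correlation). That call was lost without first tap 2 (median 1.40, adjusted p = 0.141), tumour on the intestine 1 (median 1.47, adjusted p = 0.0643) or 3 (median 1.68, adjusted p = 0.135).

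In all, 1797 genes were higher and 715 lower than in ascites. The total was 1554 without first tap 1, 1456 and 1219 without tumours on the intestine 1 and 2, and 468 among SM libraries alone. Of the 7508 genes under 1 CPM in healthy intestine, 47 were higher and 135 lower, and edgeR called 0 when adjusted over these genes alone, with 1059 at an unadjusted p under 0.05.

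Tumours on the intestine were also set against healthy intestine, to see what the tumour adds to its host tissue. No gene passed in edgeR, with 584 at an unadjusted p under 0.05 and 43 called by DESeq2. On simulated counts the fit for this comparison recovered 5 of 100 4-fold and 41 of 100 16-fold changes, so few calls do not show few differences. The median gut marker stood at 71.1%, 98.2% and 33.0% of its CPM in healthy intestine in tumours 1, 2 and 3. The 8 genes of the line stood at a median of 2.56%, 30.8% and 72.9% of their orthotopic mean there. Mesenchymal genes had a median of 1.63 (camera adjusted p = 6.77e-06, and adjusted p = 0.371 with an estimated correlation). Mesothelial and ovarian surface epithelial genes had a median of 2.01 (camera adjusted p = 0.00137, and adjusted p = 0.474 with an estimated correlation). Wt1, a transcription factor of mesothelium and ovarian surface, had 98.6 ± 92.4 CPM (SD, n = 3) against 2.31 CPM, a log2 fold change of 5.41 ± 1.83 that missed the threshold (adjusted p = 1). B cell genes had a median of -2.56 (camera adjusted p = 1.59e-09, and adjusted p = 0.371 with an estimated correlation). The epithelial list did not pass (median 0.01, camera adjusted p = 0.857), and its median was -0.36 without tumour on the intestine 1. The pancreatic acinar list had a median of 1.96 at the bounds (camera adjusted p = 0.00898, and adjusted p = 0.452 with an estimated correlation), lost without tumour on the intestine 2 (median 3.78 as fitted, adjusted p = 0.108). No member of these lists passed, also when adjusted over the list alone.

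**Figure D4:**
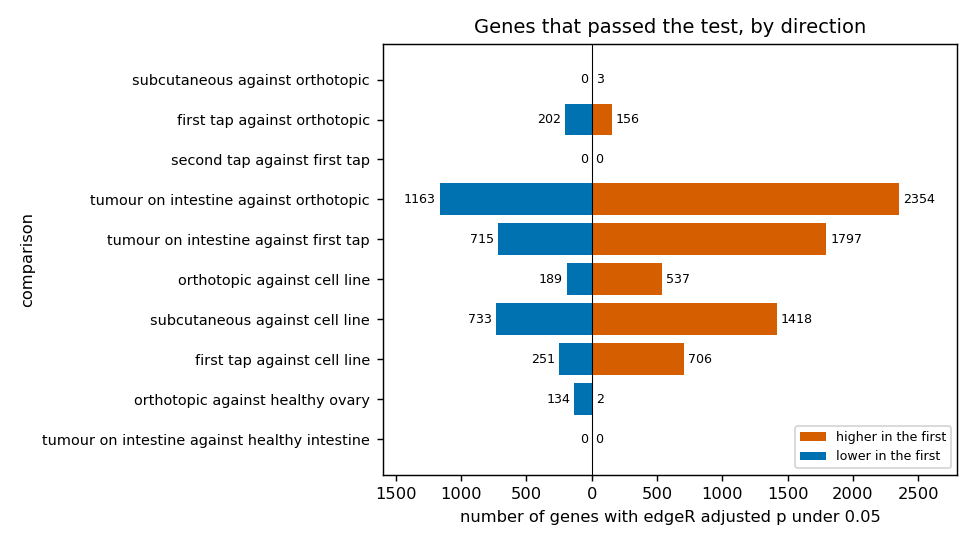
Bars give the number of genes with an edgeR adjusted p under 0.05 in each comparison, to the right for genes higher in the first group named and to the left for genes lower in it. Tumours on the intestine against orthotopic tumours have the most, 2354 and 1163, and the comparisons of the taps and of tumours on the intestine with healthy intestine have 0.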

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

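The test of whether tumour and host tissue differ by another amount at the intestine than at the ovary, and the tests of gut tissue, of an epithelial shift and of scaling, were chosen only after the results were seen. Tumours on the intestine minus healthy intestine were set against orthotopic tumours minus healthy ovary with an interaction term in edgeR, which rests on 1 library of each host tissue. It called 0 genes, with 1057 at an unadjusted p under 0.05 and no other tool run, and camera called 8 lists, none of which held with an estimated correlation (adjusted p from 0.0624 to 0.815). The difference of the epithelial list was 3.999, since it stood level with its host tissue at the intestine and below it at the ovary. The difference of the smooth muscle list was 3.123. For ovarian carcinoma genes the difference was 5.041, for granulosa and steroidogenic genes 8.641 and for oocyte genes 7.324. Keratinocyte genes differed by 5.037, B cell genes by -1.499 and MHC class II presentation genes by -1.337. These are differences of fitted values, and with members at 0 set at their bound the medians at the intestine and the ovary were 0.07 and -0.01 for keratinocyte, 0 and -6.01 for granulosa and steroidogenic, -0.16 and -6.17 for oocyte and 1.28 and -3.89 for ovarian carcinoma genes.

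The rise of the epithelial list from orthotopic tumours to tumours on the intestine was weighed. Scaling between libraries was excluded, since the list median stayed at 3.981 with library size alone. A mixture of healthy intestine and orthotopic tumour, in the share given by the gut markers, predicted the list to a median of 0.412 log2 units, so gut tissue in the samples is a candidate explanation for the rise of this list, the 1 list so tested. An epithelial shift of the tumour cells beside gut tissue cannot be told apart from gut tissue alone. Only 4 members of the list were no higher in healthy intestine than in orthotopic tumours, and of these edgeR called 0 higher and 0 lower. Epithelial levels were 6.96, 6.38 and 5.49 in tumours 1, 2 and 3, and fell in the order in which the genes of the cell line given next rose. As far as those genes follow tumour cells, this argues against a shift as the main source of the rise in these samples. In tumour on the intestine 1 the epithelial genes lay 0.95 log2 units above the mixture. The 8 genes of the cell line under 1 CPM in both healthy tissues stood at a median of 2.56% of their orthotopic mean there. They stood at 30.8% in tumour 2 and at 72.9% in tumour 3. In healthy intestine and healthy ovary, where they were chosen to be low, they stood at 1.85% and 3.15%.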

How the results depend on the processing

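The alternatives that used SM libraries alone, left out the 3 libraries with the most detected genes (subcutaneous tumour 3, first tap 3 and second tap 1), took genes under 1 CPM in intestine or the mean of both taps were chosen only after the data had been seen. Over all alternatives named genes kept their direction in every fit that gave a value. They were chosen for large folds without overlap between groups or for small p, so this is no test of direction. Of the values, 2103 were on the same side of the threshold, 496 no longer passed and 49 newly passed. List medians kept direction and side in 1428 values, kept direction but lost the call in 372, newly passed in 1 and changed sign in 30. Of the 372 lost calls, 150 came with an estimated correlation and 102 with fry, each run on the same 163 list results. DESeq2 called more genes than edgeR in all comparisons: 2300 for subcutaneous against orthotopic tumours, 2590 for the first tap and 5983 for tumours on the intestine against orthotopic tumours, 1 between the taps, 4719 for tumours on the intestine against the first tap, 3806, 6059 and 3746 for orthotopic tumours, subcutaneous tumours and the first tap against the cell line, 780 against ovary and 43 against intestine. Scaled by library size alone, edgeR called 6 genes for subcutaneous and 83 for the first tap against orthotopic tumours (19 higher, 64 lower) and 460 for orthotopic tumours against the cell line (399 higher, 61 lower). The same scaling gave 1687 higher and 1401 lower for tumours on the intestine against orthotopic tumours, 1203 and 282 for subcutaneous tumours and 589 and 97 for the first tap against the cell line, and moved the median of all genes by -0.29 to 0.25. Without a filter, 140 genes were called for subcutaneous against orthotopic tumours and 1418 for subcutaneous tumours against the cell line. Fits of only the groups compared called 0 for subcutaneous against orthotopic tumours (4332 at an unadjusted p under 0.05), 79 for the first tap and 5304 for tumours on the intestine against orthotopic tumours, and 1356 for tumours on the intestine against the first tap.

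With the series of library names as a covariate, 668 genes were called for the first tap against orthotopic tumours, and the epithelial median there was -0.008. It could not be fitted for subcutaneous tumours, which alone carry SCT names. SM libraries alone gave 0 genes for the first tap against orthotopic tumours (3398 at an unadjusted p under 0.05), 654 for tumours on the intestine against orthotopic tumours and 468 against the first tap. Their medians were -0.038 for epithelial genes in the first tap against orthotopic tumours, -0.08 for fibroblast genes between the taps and 0.217 for proliferation genes in tumours on the intestine against orthotopic tumours. Without the 3 libraries with the most genes, 1113 genes were called for subcutaneous and 1352 for the first tap against orthotopic tumours. The mesenchymal median was then -1.48 for subcutaneous against orthotopic tumours and -1.111 against the cell line, and the epithelial median -0.016 for the first tap against orthotopic tumours and 0.008 between the taps. Genes under 1 CPM in intestine, adjusted alone, gave 5 calls for tumours on the intestine against orthotopic tumours and 0 against the first tap (1059 at an unadjusted p under 0.05), and the mean of both taps gave 1023 against orthotopic tumours. With the second tap in place of the first, the median of NK and cytotoxic genes against orthotopic tumours was -0.171 and that of mesenchymal genes against the cell line 0.179. Apart from fewer genes or libraries, the cause was not tested.

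Within the 5 comparisons of replicated groups the numbers did not pair the samples, since correlations of same-numbered libraries' deviations ran from -0.549 to 0.163 and in none exceeded 0.1 for each number. First taps and subcutaneous tumours, not compared here, gave 0.329 and 0.419. With the replicate block, 8 genes were called for subcutaneous and 29 (1 higher, 28 lower) for the first tap against orthotopic tumours, the epithelial median was -0.071 for the first tap against orthotopic tumours and 0.115 between the taps, and the other comparisons between replicated groups gave 0 between the taps (123 at an unadjusted p under 0.05), 3190 and 2083.

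Without 1 library at a time, where a lone subcutaneous tumour is assumed to vary like the other groups, calls ran from 0 to 987 (without subcutaneous tumour 3) for subcutaneous and from 18 (without orthotopic tumour 1) to 793 (without first tap 3) for the first tap against orthotopic tumours, stayed at 0 between the taps (96 to 775 at an unadjusted p under 0.05), and ran from 1211 to 4085 for tumours on the intestine against orthotopic tumours and from 1219 to 2865 against the first tap. They ran from 309 to 391, 1026 to 2088 and 927 to 1140 for orthotopic tumours, subcutaneous tumours and the first tap against the cell line, from 3 to 17 against ovary, and stayed at 0 against intestine (425 to 909 at an unadjusted p under 0.05). Medians that changed sign in these fits ran from -1.484 to 0.867 for mesenchymal genes in subcutaneous against orthotopic tumours and from -1.118 to 1.176 against the cell line. Epithelial medians ran from -0.237 to 0.718 for the first tap against orthotopic tumours, -0.437 to 0.464 between the taps and -0.356 to 0.47 for tumours on the intestine against intestine. Skeletal muscle medians ran from -6.63 to 1.409 for the first tap against orthotopic tumours and -0.606 to 5.436 against ovary, immunosuppression from -0.034 to 1.839 for the first tap, and proliferation from -1.114 to 0.014 for tumours on the intestine. Between the taps, neutrophil medians ran from -2.547 to 0.684 and fibroblast medians from -0.245 to 0.61.

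Of the 10 splits of 6 libraries into 3 and 3, 1, the real one, reached 358 genes for the first tap against orthotopic tumours, 3517 for tumours on the intestine against orthotopic tumours and 2512 against the first tap, where the highest other split gave 0. Between the taps all 10 splits reached the real value of 0, and the highest other gave 99 (first taps 1 and 2 with second tap 2), which points to a structure of the samples. So few splits give no share below 0.1. Epithelial levels moved with a pseudocount of 0.25 in 4 of the 8 groups, to 1.55 in the cell line and 2.33 in orthotopic tumours, as the construction of that setting lowers genes near 0. At the depth and size of the data, the fit for subcutaneous against orthotopic tumours recovered 13 of 100 simulated 4-fold changes, and depth was not varied.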

Other observations

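Of the tests in this part, those of genes silent in the other libraries and of reads carried over between libraries were chosen only after the result was seen. Ascites libraries of both taps differed in mesothelial genes. Upk3b, a uroplakin of mesothelium, had 2407 CPM in first tap 3 and 1423 CPM in second tap 3, against 62.4 to 585 CPM in the other ascites libraries. Msln, mesothelin, had 584 and 292 CPM there against 44.0 to 158 CPM. Muc16, the CA125 antigen, had 192, 132 and 68.3 CPM in first tap 3, second tap 3 and second tap 1, and at most 23.4 CPM in the other ascites libraries, where Krt7, a simple epithelial keratin, had 13.2 to 28.1 CPM against 418, 312 and 132 CPM. First tap 2 had the highest macrophage and neutrophil list levels of the 17 libraries, 9.36 and 4.86, with Chil3, a lectin of activated macrophages, at 1792 CPM, and the matrix gene Fn1, fibronectin, at 21510 CPM.

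Hypoxia and glycolysis genes followed single libraries as well. Vegfa, the vascular growth factor, had 538 CPM in first tap 1 and 849 CPM in second tap 2, against 25.2 to 79.8 CPM in the other ascites libraries, and 880 and 1097 CPM in orthotopic tumours 1 and 3 against 214 CPM in orthotopic tumour 2. Ndrg1, a hypoxia target, had 554 and 875 CPM in first tap 1 and second tap 2, against 30.1 to 276 CPM in the other ascites libraries. Across all genes, first tap 1 and second tap 2 correlated at 0.98, above each pair of replicates within a group (0.822 to 0.967), and they are the 2 ascites libraries with S names, the other 4 having SM names. Inha had 220 to 404 CPM in orthotopic tumours against 1301 CPM in healthy ovary. Cela3b, a pancreatic elastase, had 7.24 to 20.3 CPM in orthotopic tumours and 0.0994 CPM in healthy ovary.

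Subcutaneous tumour 2 had B cell and fat genes far above subcutaneous tumour 3, with Ighm at 1575 against 35.7 CPM, Adipoq, adiponectin, at 686 against 0.982 CPM and Car3 at 4367 against 6.58 CPM. Of 10 genes of lymph node stroma and follicles listed before the test, 7 were over 4-fold higher in it than in tumour 3 and each orthotopic tumour, but 4 of these 7 (Cr2, Fcer2a, Ltb and Cxcr5) are lymphocyte genes, which restate the B cell excess, and 3 of the 6 stromal genes were that much higher, such as Glycam1 at 215 CPM. Healthy intestine expressed 8 of the 10 above 1 CPM and orthotopic tumours 4, while Ccl21a and Ccl19 were at or near 0 in all 17 libraries. The 8 genes of the cell line stood at a median of 8.26% of their orthotopic mean in tumour 2 and 183% in tumour 3. They were not chosen against skin or fat. The value in tumour 2 lay under the bound set beforehand for immune cells entering a tumour of equal tumour content. CPM is a share of a library, so entering cells would lower this value too, and it cannot decide the question. Few tumour cells in the sample, judged by the same value, is a candidate explanation. Lymph node and fat tissue cannot be told apart from other immune and fat cells, because the informative genes were too few. A difference between the animals was not tested.

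Olfactory receptor genes, which are expressed mainly in the nose, were detected as 1028, 795 and 757 of 1254 in subcutaneous tumour 3, first tap 3 and second tap 1, against 40 to 257 in the other libraries. Thinned to equal depth, the lowest of the 3 still detected 3.737 times as many as the highest other library, and its olfactory receptor CPM was 1.461 times that of the highest other library, which argues against depth and against reads carried over from the other 14 libraries. Carry-over from subcutaneous tumour 3 would bring keratinocyte genes to about 33.6% and 32.6% of their CPM there in first tap 3 and second tap 1, where their median was 4.37% and 2.50%, which argues against it. Among olfactory receptors the rho of counts with exonic length was 0.023 to 0.068 in the 3 libraries, under the bound set beforehand, which argues against genomic DNA, although the lengths came from another annotation than the one counted. With the same lengths and a lower bound, over 12315 genes nearly silent in the other 14 libraries, the lowest rho across genes, which are not independent replicates, was 0.264, and in the 3 libraries at most 0.128% of 1562 Y-linked genes among these were detected, many of which have near-identical copies, against 39.4% or more of autosomal ones, so genomic DNA of female mice as the source of these reads cannot be told apart from other sources while the length tests disagree.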
